A study of Homo sapiens with 2 samples.

How the data were processed

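Gene expression was measured on 2 single-colour Agilent arrays, each hybridised with labelled RNA from SW620 cells, an established human colorectal cancer line derived from a lymph node metastasis. Array 1 carried RNA from cells given the solvent DMSO and array 2 RNA from cells given 2 µM of the compound labelled SOX2i. Per the labels' protocols, the cells grew in medium with 10% fetal bovine serum at 37 °C and 5% CO2, treatment began 24 hours after plating, and RNA was taken after 48 hours of treatment with a column kit. Cy3-labelled cRNA was made from 0.1 µg of total RNA. Each group held 1 array, so no statistical test between the groups was possible, and no p-value is given. Both arrays shared a slide and a scan, at neighbouring positions, so the position on the slide and the group cannot be told apart.

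Per the file headers, the scanned images were processed with Agilent Feature Extraction, version 12.1.0.3, on array design 072363, with hg19 in the header's build field. The deposited scanner values used here are intensities per spot on a linear scale. The processed signal is, per the file headers, background-subtracted and corrected for trends across the array, with no scaling between arrays. Raw median spot and local background intensities and flags for outlier, saturated and well-above-background spots were deposited beside it, and other values such as these flags were taken as given. The authors' deposited value table held linear intensities. Each of its 2 columns equalled the processed signal of that array times 1 constant, 3.79 for DMSO and 4.49 for SOX2i, in all 60901 rows within a relative tolerance of 1e-06, so its values were neither log-transformed nor centred. The column medians were 46.9 and 48.4. How these constants were chosen is not given in the sources used here. They imply a scaling that differs by −0.05 on the log2 scale from the one used below.

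Each array had 62976 spots, of which 60901 were not controls. Outlier spots, 73 on the DMSO array and 86 on the SOX2i array, were left out, and none was saturated. The processed signal was taken to log2, and each array's 75th percentile over non-control spots was subtracted. Spots of the same probe were averaged, which left 58200 of the 58201 probes. A probe counted as well above background on an array when at least 50% of its spots were flagged so. Probes were named by their RefSeq accession, without versions, through an annotation table of assembly GRCh38.p14. This named 34887 probes of 25001 genes. It matched 25344 of 25833 RefSeq mRNA probes, 8100 of 8181 non-coding RefSeq probes and 1443 of 2755 RefSeq model probes. The 23313 other probes, most designed on Ensembl or long non-coding RNA catalogues, stayed unnamed. Because the header names another build, the annotation gave only names, transcript classes and the order of neighbouring genes, and no positions are printed.

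A gene was measured by its brightest probe among those well above background on both arrays and saturated on neither, which left 15512 genes, 13087 of them protein-coding. Other measured probes are given for the 30 genes described below and for any named gene whose probes differ in sign, and not for every other named gene. Differences are SOX2i minus DMSO on the log2 scale. A gene whose probes were well above background on 1 array only has a lower bound of its fold difference. The bound sets the bright level against the higher of the dim probe's own level and the lowest well-above-background level of the dim array.

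With no replicate arrays, error came from repeated spots and from different probes of the same gene. The 279 probes printed in up to 10 spots gave a median SD of 0.06 log2 for a single-spot difference between the arrays. For the 4172 genes with at least 2 measured probes, the differences of the brightest and the next probe gave an SD of 0.20 log2 for a single probe. That SD was 0.14 over the 1157 pairs with both probes at or above the median level. Neither measure covers variation between cultures, RNA preparations or labelling reactions. The number of arrays limits the precision of every value.

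Before the data were examined, 46 gene lists with 1288 genes were fixed, of which 1284 genes were found in the annotation. A list's median difference is given relative to the median of all measured genes, and its percentile is that among 10000 random lists of the same size, matched on mean level in 20 bins. A percentile at or under 2.5, or at or above 97.5, is described as outside the central 95% of random lists. Lists with under 5 measured members have counts only. The percentile describes these 2 arrays. Genes are not independent replicates, and a percentile carries no p-value for the treatment.

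The rule for named genes was also fixed beforehand. It took measured SOX family members and the 15 highest and 15 lowest differences among genes with a symbol and a mean level at or above the median of measured genes, whose measured probes all differed in the same direction. Long non-coding RNAs were left out of those 30, and 6428 genes were eligible. From each list it took members at least 2-fold apart or, failing those, the 2 to 4 furthest from 0. From the genes well above background on 1 array only it took the 5 largest bounds in each direction. Some genes that the rule names are not reported here.

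Alternatives fixed beforehand were normexp background correction with an offset of 50, quantile normalization, a median shift, no shift, a shift by the Agilent E1A spike-in probes, a loess of the difference on mean level with a span of 0.3, the deposited value table, 3 other filters on dim probes, the mean or median over a gene's probes, thresholds of 1.5-fold and 3-fold, and random lists not matched on level. Lists under an alternative were set against 2000 random lists, except 10000 for unmatched ones. The files hold no mean spot signal, so normexp used the median spot signal in its place. A 75th percentile over probes well above background on both arrays was added after the data were seen.

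The steps from spots to genes and lists were tested on simulated data, made from the real DMSO array with 200 changed genes among 16078. All 3-fold changes were recovered at 2-fold or more in both directions (100%), 3% of 1.5-fold changes passed 2-fold, and 6 unchanged genes did. A planted list of 40 genes shifted by 0.15 reached percentile 100, and 6% of 200 unchanged lists fell outside the central 95%. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 was used, with R 4.3.3 and limma 3.58.1 for normexp.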

Results

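The comparison asked how the compound labelled SOX2i alters gene expression across the genome in SW620 colorectal cancer cells. The series as a whole concerns a pyrrole-imidazole polyamide, a synthetic DNA-binding molecule, designed against SOX2. SOX2 is a transcription factor of embryonic and adult stem cells. A single array was available for DMSO and another for 48 hours of 2 µM SOX2i, so every value compares 2 arrays without replicates. The 75th percentile of the processed signal was 275.6 on the DMSO array and 225.1 on the SOX2i array, and 52.4% and 50.5% of non-control spots were well above background. Levels were compared for 15512 genes.

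SOX2 mRNA was abundant on both arrays and differed little between them. The single SOX2 probe (A_23_P401055) read 8354 with DMSO and 6523 with SOX2i before scaling, and its mean level lay at percentile 90.8 of measured genes. After scaling to the 75th percentile the SOX2i array stood at 0.956 times the DMSO level, a log2 difference of −0.06. This is smaller than the SD of a single bright probe, 0.14 log2. The difference was −0.36 without scaling and −0.25 with scaling by spike-in RNA.

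Of the 19 SOX family genes, 7 were measured on both arrays and the other 12 were not well above background on either. SOX9, a factor of intestinal crypt cells, differed by −0.07, SOX4 by −0.15, SOX12 by −0.09 and SOX5 by −0.07. SOX8 differed by 0.23. SOX13 gave 0.24 by its brightest probe and −0.11 by another. The family's median was −0.11 relative to all measured genes, at percentile 15.98 of matched random lists. POU5F1, which encodes the SOX2 partner OCT4, read 0.00 by its brightest probe and −0.22 by another.

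Across all measured genes the arrays were alike. Levels correlated with Pearson's r of 0.997 across genes, which are not independent replicates. The median difference was 0.04, the quartiles were −0.11 and 0.19, and 15057 genes (97.1%) lay within 1.5-fold. Scaling sets the centre of this distribution. Without scaling all differences were lower by 0.29, and scaling by the spike-in RNA lowered them by 0.19, so the sign of a small difference in a single gene depends on the scaling. Group values are therefore given relative to the median of all genes.

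At least 2-fold, 19 genes were higher and 12 lower with SOX2i, and all 31 lay below the median level. The median unscaled signal of the higher genes was 13.7 with DMSO and 27.3 with SOX2i, and that of the lower genes was 34.7 and 13.4. The disagreement between probes of the same gene would alone give about 2.87 genes in each direction, an estimate that rests on genes with several probes. It groups pairs by their dimmer probe but averages the error of both probes, so it may be too low for such dim genes. The split of higher to lower genes turned on the scaling. It was 3 to 80 without scaling, 4 to 31 with spike-in scaling, 10 to 16 with a median shift, 12 to 14 in the deposited table, 13 to 16 after loess and 14 to 13 after quantile normalization. With normexp background correction no gene reached 2-fold in either direction, so none of the genes named next kept a 2-fold difference there. That setting adds an offset of 50, above these median signals, which by itself shrinks the folds of dim genes. Its count therefore cannot test the 2-fold differences. Admitting probes well above background on at least 1 array gave 106 genes at least 2-fold higher in SOX2i and 112 lower, and no background filter gave 1028 and 443.

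Among genes measured on both arrays, the only one beyond 3-fold was PCDHA11, a protocadherin of neuronal contacts, with signals of 11.3 and 33.9 and a fold of 3.66. It and the next genes are named here because their values stood out. PIEZO2, a mechanically gated ion channel, was 2.69-fold higher. MATN1, a cartilage matrix protein, was 2.25-fold higher, with 0.99 and 1.17 log2 by its 2 probes. CCDC33 was 1.01 log2 higher by its brightest probe and −0.29 by the other. ZNF354A, a zinc finger protein, was 2.48-fold lower, TRIM5, a retroviral restriction factor, 2.43-fold lower and SLC6A3, the dopamine transporter, 2.40-fold lower.

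**Figure D1:**
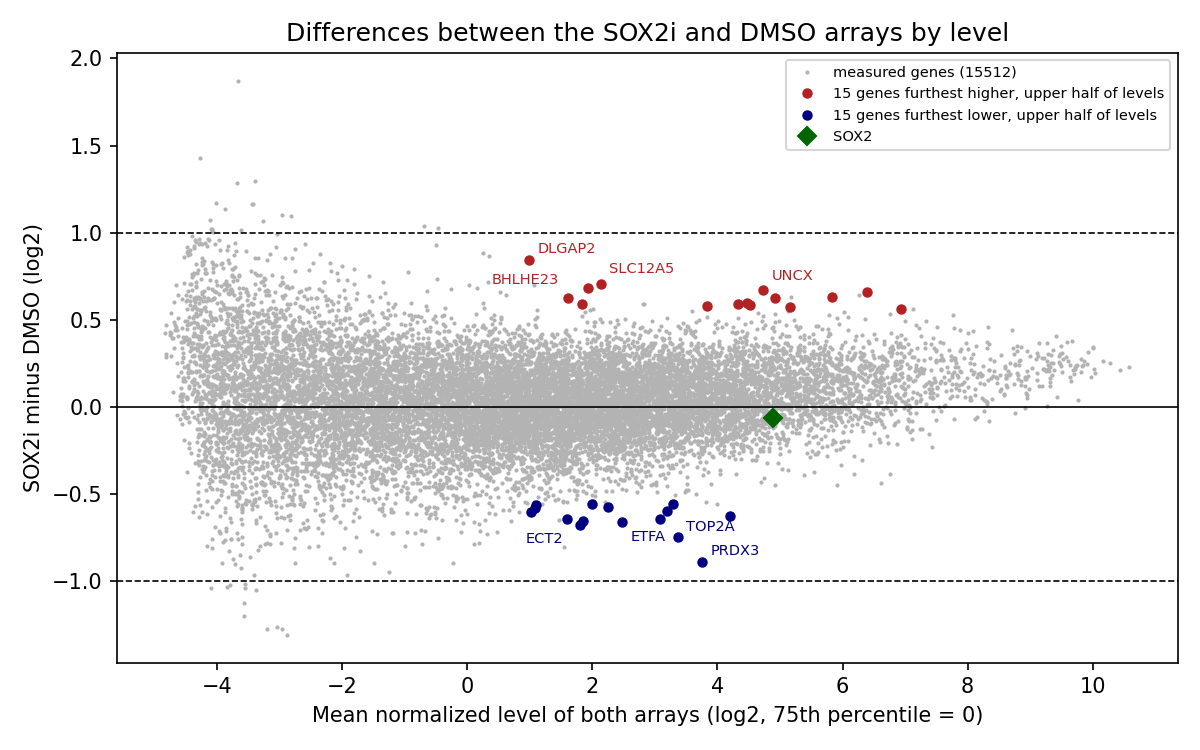
Difference between the SOX2i and DMSO arrays (vertical axis, log2) against the mean normalized level of both arrays (horizontal axis, log2, 0 at the 75th percentile) for 15512 measured genes. Red and blue points mark the 15 highest and 15 lowest named genes, the green diamond marks SOX2 at −0.06, and the dashed lines mark 2-fold, beyond which 19 genes lie above and 12 below.

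Among genes in the upper range of levels, where probes of a gene differed least, none reached 2-fold with this scaling. Without scaling 3 were at least 2-fold lower, among them PRDX3 (−1.18) and TOP2A (−1.04), and PRDX3 alone was (−1.08) with spike-in scaling. Under the naming rule the 15 furthest higher lay between 0.56 and 0.84 and the 15 furthest lower between −0.89 and −0.56, against a single-probe SD of 0.14. They are the extremes of 6428 eligible genes, so that SD does not show by how much they exceed what selection alone would pick.

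The lower genes included 2 of cell division. TOP2A, the topoisomerase that untangles chromosomes, was 1.68-fold lower (3682 to 1788 in signal), and ECT2, which starts cytokinesis, differed by −0.68. PRDX3, a mitochondrial peroxidase, showed the largest difference of the 30, at 1.85-fold lower (5059 to 2231). Other genes of mitochondrial proteins were ETFA, an electron transfer flavoprotein subunit (−0.66), ABCB10, an inner membrane transporter (−0.58 and −0.91 by its 2 probes), and POLG2, a subunit of the mitochondrial DNA polymerase (−0.56). NUP160, a nuclear pore protein, differed by −0.65 and HMGN4, a nucleosome-binding protein, by −0.66. BIRC2, an inhibitor of apoptosis, differed by −0.61 and VCL, the focal adhesion protein vinculin, by −0.60. ECPAS, a proteasome adaptor, gave −0.57 by its brightest probe and −0.10 by another. RBM26 differed by −0.56 and PPP2R5C, a phosphatase subunit, by −0.56. The pseudogenes SUGT1P1 (−0.65) and AFG3L1P (−0.63, and −0.59 by its other probe) completed the group.

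The higher genes were led by DLGAP2, a postsynaptic scaffold protein, at 1.80-fold (407.5 to 597.7 in signal), and SLC12A5, the neuronal potassium-chloride cotransporter, at 1.63-fold. The developmental transcription factors BHLHE23 and UNCX followed at 0.68 and 0.67. CCM2L differed by 0.66 and EMILIN1, an elastic fibre protein, by 0.62. NFKBIL1 gave 0.63 and 0.33 by its 2 probes, and FBRSL1 0.63 and 0.20. CLEC11A, a secreted growth factor, differed by 0.59, the receptor gene UTS2R by 0.59, and the mitochondrial iron-sulfur protein gene CISD3 by 0.58. The non-coding RNAs SNORA5A and RNA5-8SN5 differed by 0.59 and 0.58. TFF3, the trefoil peptide of goblet cells, was 1.48-fold higher (27708 to 33451), and its 3 probes spanned 0.47 to 0.56.

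Of the 46 gene lists, 45 had enough measured members for a percentile. Outside the central 95% of matched random lists lay 12, 6 on the low side and 6 on the high side. Random draws of genes would give 2.25. That number takes genes as independent, so it is not what 2 arrays of like cultures would give. Some lists share members. The members named for each list are those furthest from 0, a rule that favours dim genes. In the dimmest 10% of measured genes the SD of the differences was 0.39, against 0.16 in the brightest 10%. Several named members had signals near background, so they need not lead their lists. No member of any list was 2-fold apart with this scaling, while 3 were 2-fold lower without scaling and 1 with spike-in scaling.

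Genes of G2 phase and mitosis were lower as a group with SOX2i. All 41 were measured, 30 lay below the median of all genes, and the list's median was −0.13, at percentile 0. Beyond TOP2A and ECT2, the spindle checkpoint gene MAD2L1 differed by −0.48 and the kinetochore gene NUF2 by −0.35. Genes of the G1/S transition and DNA replication, with 41 measured, had a median of −0.02 at percentile 11.1, with RFC3 at −0.41 and RRM2 at −0.38. Replication-dependent histone genes were higher as a group. All 29 measured lay above the median of all genes, the list's median was 0.24 and its percentile 100, with H3C15 at 0.46, H2BC9 at 0.45 and H4C4 at 0.41. Probes of histone genes can share sequence, so these members may not be separate measurements. Repair and damage-response genes had a median of −0.07 at percentile 4.51 (40 measured, PALB2 −0.52, H2AX 0.34), p53 targets 0.01 at 66.0 (28 measured, CCNG1 −0.56, SESN1 −0.54, PHLDA3 0.51), and apoptosis regulators 0.00 at 57.3 (33 measured, BIRC2 −0.61, BOK 0.58).

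Cytoplasmic ribosomal protein genes were higher as a group, 46 of 48 above the median of all genes, with a list median of 0.21 at percentile 100. RPS28 differed by 0.41, RPLP1 by 0.38 and RPS27 by 0.37. This group left the outer range after quantile normalization (percentile 66.8) and after loess (96.1). Ribosome biogenesis and MYC target genes had a median of 0.00 at percentile 10.6 (33 measured, RRP9 0.31, TFRC −0.28).

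**Figure D2:**
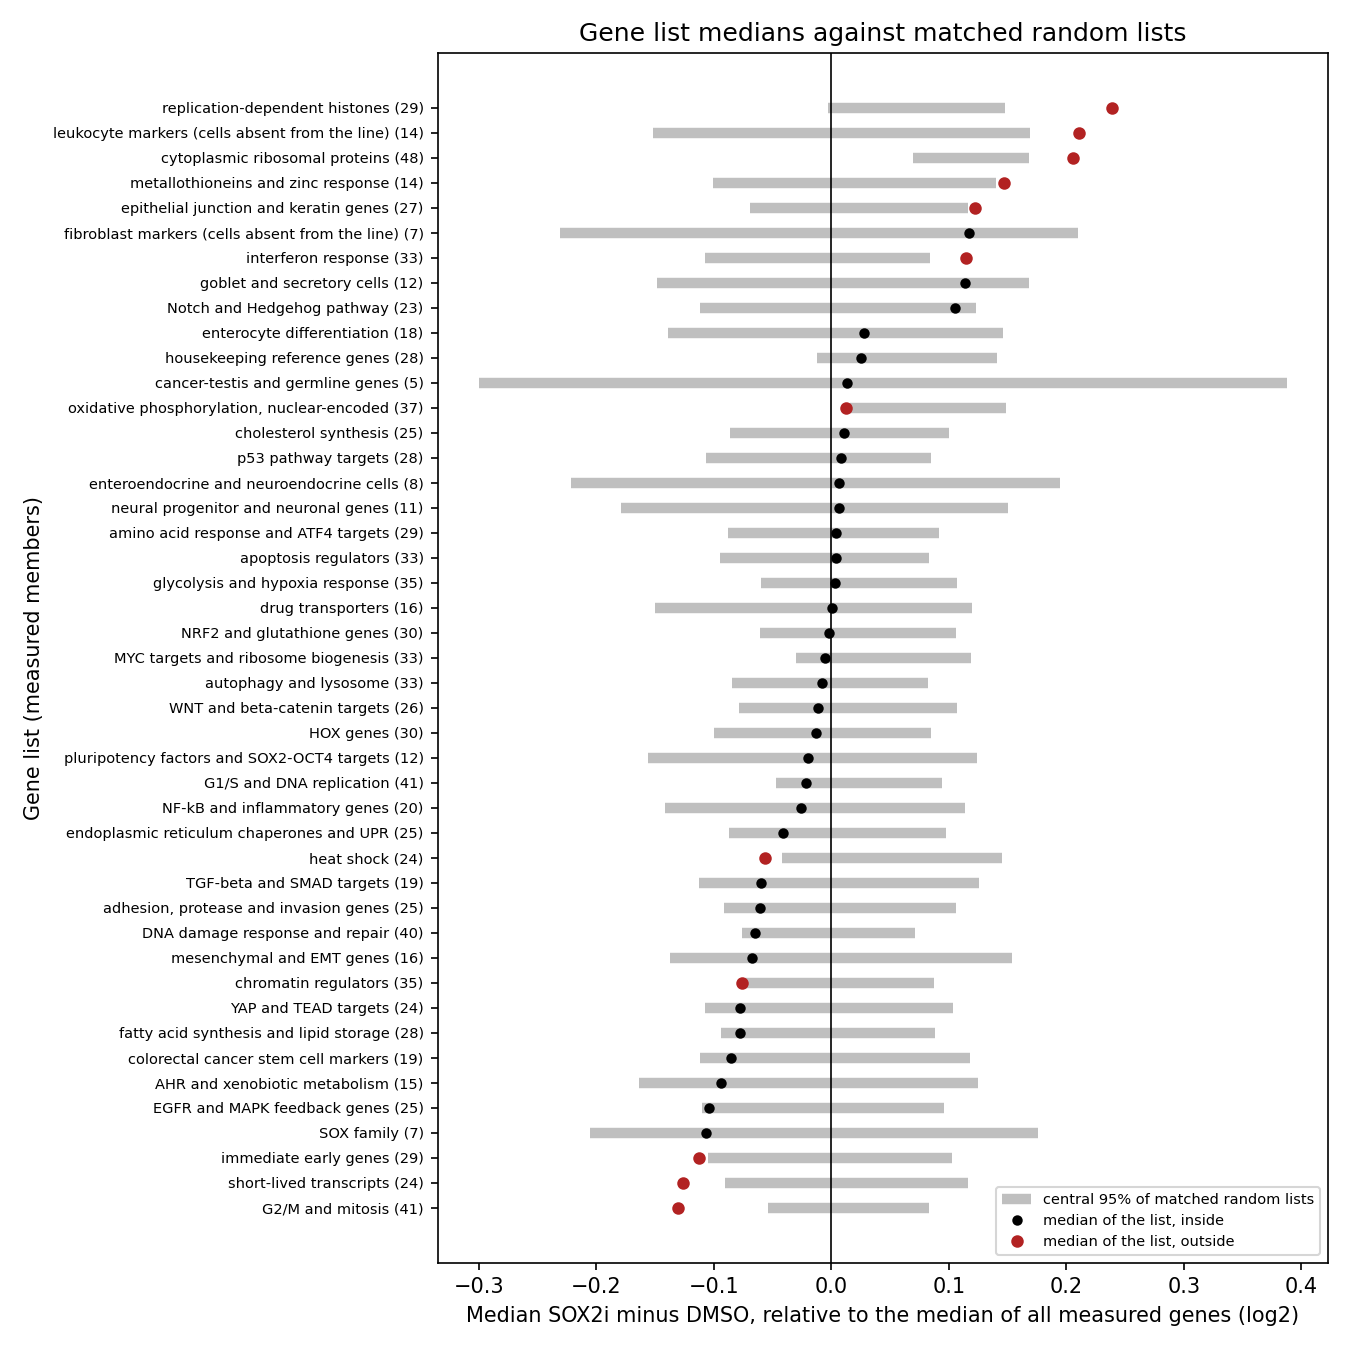
Median difference of each of 45 gene lists (horizontal axis, log2, relative to the median of all measured genes), with the number of measured members in brackets. Grey bars span the central 95% of 10000 random lists matched on level, and the 12 red points lie outside, from G2/M and mitosis at −0.13 to replication-dependent histones at 0.24.

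Lists tied to stem cells and spread stayed within the range of random lists. Colorectal cancer stem cell markers had a median of −0.09 at percentile 6.14, with 13 of 19 below the median of all genes. Its members went both ways, with the chemokine receptor CXCR4 at 0.50, the crypt stem cell receptor LGR5 at 0.47, and PROM1 (CD133) at −0.43. ALDH1A1 gave −0.37 by its brightest probe and 0.35 by the other. Pluripotency factors and SOX2-OCT4 targets had a median of −0.02 at percentile 46.4 (12 measured, KLF4 −0.55, SALL4 0.38). Mesenchymal and EMT genes stood at −0.07 and percentile 14.6 (16 measured, CCN1 −0.44, CCN2 −0.41, COL1A1 0.32), and adhesion, protease and invasion genes at −0.06 and 8.64 (25 measured, MMP11 0.50, L1CAM −0.39). Epithelial junction and keratin genes were higher as a group, 17 of 27 above the median of all genes, at 0.12 and percentile 98.3. The tight junction genes TJP3 and CLDN3 differed by 0.92 and 0.41, TJP3 at low signals of 23.9 with DMSO and 37.0 with SOX2i. This list fell to percentile 94.7 after quantile normalization.

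Transcripts that turn over or respond to signals quickly were lower in 2 lists. Immediate early genes, 24 of 29 below the median of all genes, had a median of −0.11 at percentile 1.72, with KLF4 at −0.55, CCN1 at −0.44 and CCN2 at −0.41. Restricted to genes at or above the median level, the list stood at 3.90. Short-lived transcripts, some of them also immediate early genes, had a median of −0.13 at percentile 0.35, 18 of 24 below the median of all genes. The survival gene MCL1 differed by −0.42 and the kinase gene PIM1 by −0.36. EGFR and MAPK feedback genes had a median of −0.10 at percentile 3.15 (25 measured, HBEGF −0.46, SPRED2 −0.46), YAP and TEAD targets −0.08 at 7.96 (24 measured, LATS2 −0.53, WWTR1 −0.53), TGF-beta and SMAD targets −0.06 at 13.5 (19 measured, CCN2 −0.41, COL4A1 −0.32, COL4A2 0.29), WNT and beta-catenin targets −0.01 at 28.8 (26 measured, LGR5 0.47, DKK1 −0.36), and Notch and Hedgehog genes 0.11 at 94.7 (23 measured, HEYL 0.50, HES5 0.50, GLI2 0.43, PTCH1 −0.39). NF-kB and inflammatory genes stood at −0.03 and 44.2 (20 measured, IL18 −0.64, IL32 0.39).

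**Figure D3:**
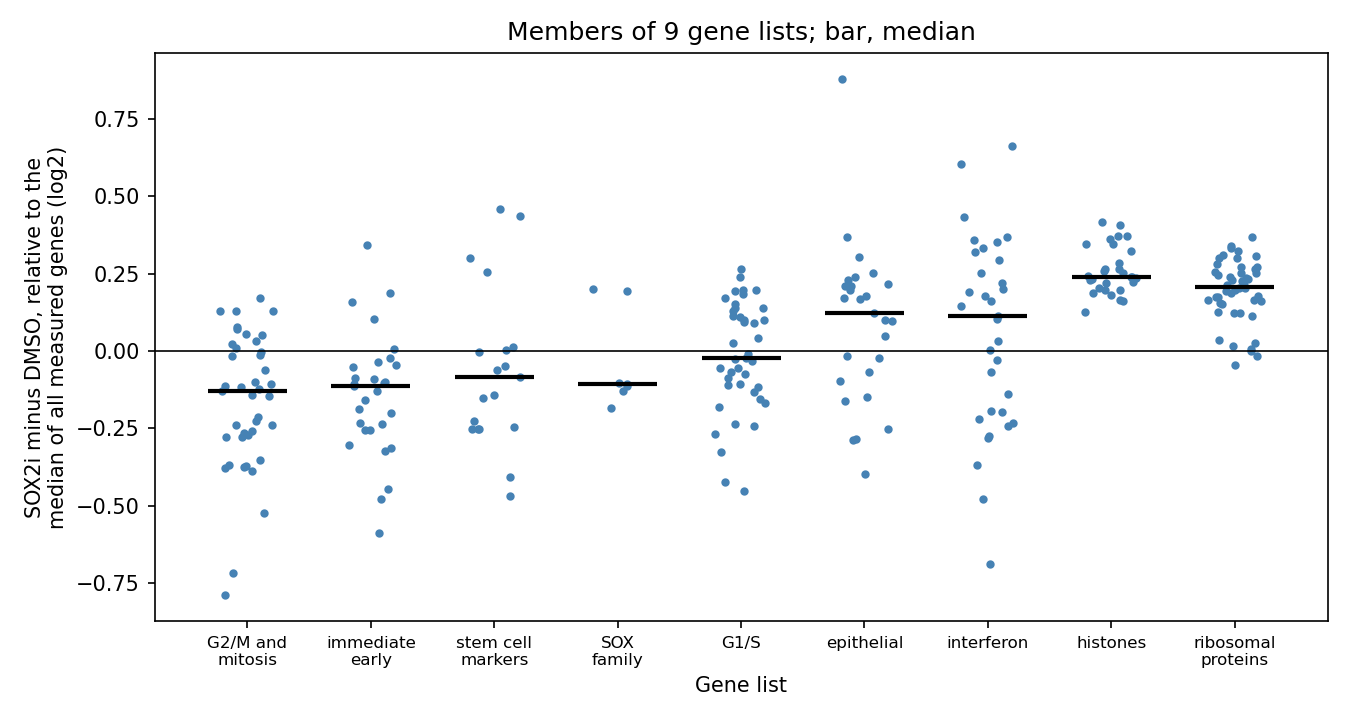
Differences of single genes in 9 gene lists (vertical axis, log2, relative to the median of all measured genes), 1 point per measured gene, with a bar at each list's median. All 29 histone genes lie above 0, while 30 of 41 G2/M genes lie below it.

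Interferon response genes were higher as a group, at 0.11 and percentile 99.6, with 20 of 33 above the median of all genes. The antiviral enzyme gene OAS2 gave 0.70 by its brightest probe and 0.09 by the other, BST2 0.64 and 0.26, and the RNA sensor gene IFIH1 −0.65. Heat shock genes were lower, 16 of 24 below the median of all genes, at −0.06 and percentile 1.10. The chaperone genes BAG3, DNAJA1 and HSPA8 differed by −0.57, −0.45 and −0.39, while CRYAB differed by 0.77. The heat shock list left the outer range after quantile normalization (percentile 5.50) and against random lists not matched on level (15.6). Metallothionein and zinc genes were higher, 10 of 14 above the median of all genes, at 0.15 and percentile 98.0, with MT1H at 0.43 and MT1M at 0.29. These 10 were all metallothioneins, whose probes may share sequence and so may not be separate measurements. The 3 measured zinc genes of the list that are not metallothioneins differed by −0.27 to −0.10. The whole metallothionein and zinc list stayed in the outer range in 10 of 14 alternatives, the lowest percentile being 96.9. Endoplasmic reticulum chaperones stood at −0.04 and 15.9 (25 measured, PDIA6 −0.38, DERL1 −0.34, SDF2L1 0.34), ATF4 targets at 0.00 and 52.2 (29 measured, NUPR1 0.53, GARS1 −0.46), NRF2 and glutathione genes at 0.00 and 27.6 (30 measured, ME1 −0.53, NQO1 −0.42), and AHR and xenobiotic genes at −0.09 and 16.4 (15 measured, CYP1A1 −0.64, NQO1 −0.42).

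Nuclear-encoded oxidative phosphorylation genes had a median of 0.01, yet lay at percentile 1.92, below the 0.02 to 0.15 that spanned the central 95% of matched random lists. Of 37 measured, ATP5F1C differed by −0.54, SDHD by −0.41 and NDUFV1 by 0.42. Chromatin regulators were lower, 23 of 35 below the median of all genes, at −0.08 and percentile 2.09, with TET2 at −0.30 and BRD2 at 0.31. Both lists returned to the inner range under several settings. Glycolysis and hypoxia genes stood at 0.00 and 31.0 (35 measured, ALDOC 0.48, BNIP3 −0.46), cholesterol synthesis at 0.01 and 54.4 (25 measured, TM7SF2 0.38, PMVK 0.35, MSMO1 −0.34), fatty acid and lipid storage genes at −0.08 and 5.38 (28 measured, ACSL4 −0.72, FABP6 0.71), autophagy and lysosome genes at −0.01 and 42.1 (33 measured, MAP1LC3A 0.50, ATG3 −0.45), and drug transporters at 0.00 and 60.0 (16 measured, SLCO1B3 −0.89, SLC22A3 −0.55).

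Differentiation lists lay within the range of random lists. Goblet and secretory genes stood at 0.11 and percentile 89.1, 10 of 12 above the median of all genes, with TFF3 at 0.56 and MUC13 at −0.48. Enterocyte genes stood at 0.03 and 63.5 (18 measured, KLF4 −0.55, APOA1 0.53), enteroendocrine genes at 0.01 and 57.0 (8 measured, CHGA 0.49, GCG −0.34), neural genes at 0.01 and 59.8 (11 measured, HES5 0.50, L1CAM −0.39), HOX genes at −0.01 and 46.2 (30 measured, HOXB7 0.41, HOXA10 0.31 and −0.14 by its 2 probes), and cancer-testis genes at 0.01 and 42.5 (5 measured, SSX2 0.25, MAGEA6 −0.14). Housekeeping genes stood at 0.03 and 15.5 (28 measured, B2M −0.41, CHMP2A 0.31).

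Markers of cells that a pure line should lack were also examined. Leukocyte markers were higher, 12 of 14 measured above the median of all genes, at 0.21 and percentile 99.3, with CD79A at 0.46 (956.4 to 1077 in signal), CD14 at 0.43 and CD4 at 0.43. Those not above it were PTPRC, at −0.02 by its brightest probe and 0.28 by the other, and LCP1 at −0.003. After loess the leukocyte markers stood at percentile 96.2, inside the central range. At or above the median level only 3 were measured, too few for a percentile. A pure line should lack these cells, so a list can reach the outer range here without a change in what it stands for. This limits what the other lists that were higher as a group can be taken to mean. Fibroblast markers stood at 0.12 and 86.9 (7 measured, COL5A1 0.46, FBLN1 0.33). Of the endothelial markers 4 were measured, 3 above the median of all genes, with VWF at 0.43 and NOS3 at 0.28.

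Some genes were well above background on 1 array only, 561 on the DMSO array and 174 on the SOX2i array. With the main scaling the bound lay above 1 for 390 of the 561 and for all 174. The remaining genes of the DMSO array were therefore not shown to be higher with DMSO. The bound reached 2-fold for 10 genes on the DMSO array and 39 on the SOX2i array, and this split turned on the scaling. It was 36 to 8 without scaling, 22 to 14 with spike-in scaling and 24 to 13 after loess. No bound reached 2-fold with normexp, whose offset of 50 by itself shrinks folds at such low signals and so cannot test them. On the DMSO array the largest bounds were PNLDC1, an RNA-trimming nuclease of the germline, at least 4.07-fold higher with DMSO, EYA4 at least 2.28-fold, GK5 at least 2.26-fold, SPANXB1 at least 2.20-fold and CDC42EP3 at least 2.14-fold. On the SOX2i array they were OR6W1P, an olfactory receptor pseudogene, at least 3.53-fold higher with SOX2i, RNASE13 at least 2.96-fold, LOC112268140 at least 2.79-fold, TRIM50 at least 2.76-fold and HEPH, a copper-dependent ferroxidase, at least 2.75-fold. All these signals were low, and the highest was 42.5, for PNLDC1 with DMSO.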

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

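Probes without a gene name were outside the comparison above, and some gave more signal with SOX2i than with DMSO. Of 6907 unnamed probes well above background on both arrays, 38 were at least 2-fold higher and 10 at least 2-fold lower, a split that turned to 7 and 64 without scaling, 12 and 28 with spike-in scaling and 1 and 0 with normexp. The normexp offset of 50 by itself shrinks the folds of dim probes. The 5 furthest higher are given here because they exceeded the control array most. A_22_P00013089 was 2.06 log2 higher, with unscaled signals of 45.6 with DMSO and 155.1 with SOX2i. A_21_P0007205 was 1.98 higher (9.52 and 30.8), A_22_P00016445 was 1.64 higher (12.4 and 31.5), A_33_P3325102 was 1.46 higher (34.3 and 77.3) and A_21_P0001433 was 1.39 higher (11.2 and 24.0). Among the 1204 unnamed probes at or above the median level of measured genes, differences spanned −0.70 to 0.87. The genes behind these probes are not analysed here.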

How the results depend on the processing

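With 1 array per group no array could be left out, no paired or slide-blocked fit could be made, and the added 75th percentile (chosen after seeing the data) gave the same counts of 19 and 12. No paired analysis was possible because each group held 1 array. Signal over background limits the counts, since all genes at 2-fold were dim with the main scaling (3 at or above the median level were lower with no shift and 1 with spike-in scaling), and the 10 and 39 genes with 2-fold bounds stood near background. SOX2 ranged from −0.06 to −0.36 (no shift, by construction the same constant for every gene), and as it has 1 probe, only normexp (−0.10), quantile normalization (−0.14) and loess (−0.13) tested its sign. Counts of genes at least 2-fold higher in SOX2i, and of genes at least 2-fold lower in SOX2i, moved by over 1.5 times as follows. They were 0 and 0 with normexp, which changed the input signal, the background method and the offset together, 3 and 80 with no shift, and 4 and 31 with spike-in scaling. The normexp offset of 50 by itself shrinks the folds of dim genes, so its counts of 0 do not test them. The median shift gave 10 higher and the deposited values 12 higher. Counting probes well above background on at least 1 array gave 106 and 112, no background filter 1028 and 443, and the filter at or above the median level 0 and 0. Thresholds of 1.5-fold and 3-fold gave 289 and 166, and 1 and 0. Quantile normalization, loess and the mean or median over probes stayed within 1.5 times. Genes well above background on one array only, by array: with a bound of at least 2-fold, the DMSO array had 0 with normexp, 36 with no shift, 24 after loess and 22 with the spike-in shift, and the SOX2i array 0, 8, 13 and 14. Filters and the choice among probes do not apply to these bounds. The cause was not tested for the median shift and the deposited table beyond their constant shifts.

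Of the 12 lists outside the range of random lists, 4 stayed outside in all 14 alternatives, of which the 5 constant shifts cannot move a list: G2/M and mitosis (percentiles 0 to 0.245), short-lived transcripts, histones and interferon response. The median of oxidative phosphorylation, nuclear-encoded relative to all genes, turned to −0.0413 with normexp, −0.0370 with quantile normalization, −0.0374 after loess and −0.0730 with no background filter, and that list stayed outside in 8 alternatives, chromatin regulators in 7 and metallothioneins in 10. The cause was not tested. Leukocyte markers had 3 measured members at or above the median level and so no percentile there. Among the 30 bright named genes, 35 of 390 values moved by 1 SD or more, and all kept their sign. Leaving out the scaling lowers every gene by the same 0.29, which counted as a move, so the 35 are not separate changes. The SD used here was above the spike-in shift of 0.19, which did not count as a move, so it was not the 0.14 of bright probe pairs. Filters, constant shifts of at most 0.29 and the mean or median over probes could not turn the sign. Loess and quantile normalization correct trends with level, and the medians by level ran only from −0.005 to 0.137. These genes differed by 0.56 or more in size, so neither setting could readily turn the sign. At most normexp tested it.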

Other observations

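The transcript classes, their families and the 2 added checks named below (a resampling of neighbours and a removal of gene families) were chosen after the results were seen. The gene lists and the other tests were set out before their values were computed, although the 3 patterns were picked after a first look at the differences.

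Small structural RNAs were higher as classes, though only the class annotated as small nuclear RNA was shifted throughout. All 15 measured genes with that annotation lay above the median of all genes, with a class median of 0.22 relative to it and a percentile of 99.8 among matched random lists. Of these 15, 8 are SNAR genes of a single family, whose probes may share sequence, so they may not be separate measurements. Small nucleolar RNAs, which guide the modification of ribosomal RNA, stood at 0.09 and percentile 100, with 132 of 211 above the median of all genes. They went both ways. SNORA genes lay above it in 70 of 93 cases and SNORD genes in 62 of 118. SNORA79 differed by 1.02 (140.2 to 233.0 in signal), SNORA63 by 0.54, SNORA23 by 0.46 and the lowest SNORA gene, SNORA70F, by −0.26. SNORD genes ran from SNORD53 at −0.76 and SNORD103A at −0.61 to SNORD105 at 0.60 and SNORD92 at 0.76, with a median of 0.02 relative to all genes. Signals were low at both ends, 26.3 with DMSO and 12.7 with SOX2i for SNORD53, and 10.1 and 14.0 for SNORD92. The lowest well-above-background signals of the 2 arrays were 8.05 and 8.54. Other small non-coding RNAs, 16 of 20 above the median of all genes, stood at 0.23 and percentile 100, and among them SCARNA14 differed by 1.04 and SCARNA3 by −0.50. Long non-coding RNAs stood at 0.06 and percentile 100 over 1774 genes, transcribed pseudogenes at −0.04 and 0.31 over 382, and protein-coding genes at −0.01 and percentile 0 over 13087. The labelling kit primes on poly(A) tails, which most of these small RNAs lack, and what their probes read was not tested.

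The lower level of mitotic genes with SOX2i stayed under 2 of 3 technical tests. An intensity trend between the arrays was argued against, since the list stayed at percentile 0 after the loess, with a median of −0.14. Error of single probes was argued against too, because the other measured probes of 10 of these genes had a median of −0.23 at percentile 0.59. A regional property of the genome, such as base composition, cannot be told apart from a group effect, since 82 neighbouring genes had a median of −0.01 at percentile 28.4. That value passed the bound of 25 set beforehand for excluding it, but the resampling of these neighbours, added afterwards, put the percentile anywhere from 0.350 to 83.1. A response of the cells to SOX2i, a difference between the 2 cultures and the base composition of the transcripts themselves stay open and untested.

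Ribosomal protein and histone genes were both higher, and the loess separated them. For ribosomal proteins an intensity trend remains a candidate explanation. The loess brought the median from 0.21 (random lists 0.07 to 0.17) to 0.04 (random lists −0.04 to 0.05), at percentile 96.1. All 48 of these genes lie in the brightest 10% of measured genes, where the median was itself 0.10 relative to all genes. Why matching in 20 bins left this list outside was not tested. For histones the trend was argued against, with a median of 0.20 and a percentile of 100 after the loess. Error of single probes was argued against for both, since other probes of 26 ribosomal protein genes stood at percentile 99.5 and those of 7 histone genes at 100. Most replication-dependent histone mRNAs also lack poly(A) tails, so a difference in priming between the labellings stays open for them, as for the small RNAs. Shared sequence among histone probes, a response to SOX2i and a difference between cultures stay open too, and none of these was tested. A regional property such as base composition also stays open for both groups, since their genomic neighbours were not tested.

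How much of the spread over genes is real is the third question. Differences of the brightest and the next probe correlated with Pearson's r of 0.31 (Spearman's rho 0.33) over 4172 genes, too high for probe error alone as set out beforehand (under 0.2) and too low to exclude it as the main source (above 0.5). The SD of a single probe from this disagreement was 0.20, and the SD of the brightest probes' differences over these genes was 0.21. The single-probe SD averages the error of the brightest probe with that of the dimmer next probe. It may therefore be too high for the brightest probe alone. Setting these SDs side by side cannot show how much of the spread came from probe disagreement. Over 1157 pairs with both probes bright, r was 0.51, and the SDs were 0.14 and 0.18. Adjacent measured genes correlated at 0.13 over 15487 pairs, against at most 0.02 in 1000 shuffles, and at 0.13 after removing pairs whose symbols share their first 3 letters (13956 pairs left). This is consistent with part of the spread following a regional property such as base composition, which could be technical, and shared regulation of neighbours would give the same. Genes are not independent replicates. No probe or transcript sequence was among the data used here, so composition itself was not tested.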
